A study of Drosophila melanogaster with 16 samples.

How the data were processed

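RNA from dissected adult brains of Drosophila melanogaster was measured on single-colour arrays. Per the labels, the brains came from prickle-spiny legs (pk^sple1) mutants, a line described there as bang sensitive, and from Oregon-R controls. Bang-sensitive flies have seizures or paralysis after a mechanical shock. Each genotype had 2 biological replicates, and each of these was read on 4 technical arrays, which gave 16 arrays. Per the labels' protocols, RNA was extracted with TRIzol, purified on columns and copied into double-stranded cDNA with random hexamers, and the cDNA was labelled with Cy3.

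The deposited table holds 1 intensity per transcript and array, on a linear scale, for 21051 FlyBase transcript IDs. Per the submitters' processing notes, the values were made with RMA, whose version, platform and annotation release are not given in the sources used here. RMA output is usually on the log2 scale. The deposited intensities were not: they ran from 27.42 to 45946. Whether they were put back on the linear scale or scaled further is not given in the sources used here. The median intensities of the 4 arrays were 1799, 1776, 1728 and 1721 for control replicate 1, and 1683, 1669, 1685 and 1670 for control replicate 2. They were 1726, 1721, 1722 and 1742 for sple replicate 1, and 1731, 1602, 1632 and 1638 for sple replicate 2. No 2 arrays held identical values.

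A floor of 27.42 was held by 4414 transcripts on all 16 arrays, and no other transcript touched it on any array. The next value above the floor was 54.84. The plan was to let all transcripts enter. The 4414 were left out once the floor was seen, because they carry no spread, and keeping them was run as an alternative. This left 16637 measured transcripts.

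Log2 of the deposited intensity was taken with no added constant. The 4 technical arrays of a biological replicate share its RNA and were averaged, so that each genotype entered with n = 2. Sple and control were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), and p-values were adjusted by Benjamini-Hochberg, with 0.05 as the threshold. The test, the samples, the averaging, the alternatives and 30 gene lists were fixed before the data were examined. An exact two-sided permutation test of 2 against 2 cannot give a p below 0.333. Intervals at 95% come from the moderated standard errors. The number of biological replicates limits the precision. A count of transcripts whose replicates were at least 2-fold apart between genotypes, that is 1 log2 unit between the nearest pair of replicate means, was added after the data were seen.

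The table names transcripts by ID alone. Names were taken from a gene table of the Release 6 plus ISO1 MT assembly, in which 49 of the IDs stand among the synonyms of a gene. Of these, 44 were measured and 5 were at the floor. The 44 comprised 16 transcripts listed under 1 gene and 28 listed under several genes, which are reported as a group and not named. The other 21002 IDs are not named here. The gene pk was not among the genes matched, so its level is not reported here. None of the 30 gene lists had a measured member with a name, so the lists could not be tested. Transcripts stand in for genes in every count. The rule fixed for named genes took, if fewer than 5 passed the threshold, those with the highest and the lowest log2 difference among transcripts with an unadjusted p under 0.01 whose replicates did not overlap between genotypes. With IDs alone, it was held to 2 transcripts in each direction. The 5 highest and 5 lowest of the 16 named transcripts are also given. That choice was made after their values were seen.

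The fits were tested on simulated data for this comparison with 16637 transcripts, of which 200 were changed by known amounts. With the observed spread between replicates, the fit on averaged arrays called 1.49% of changes of 1 log2 unit, 20.9% of changes of 2 log2 units and 63.6% of changes of 3 log2 units. With no changed transcripts it made 0 calls. A fit of all 16 arrays with the replicate as a random block made 625 calls in that simulation without changes, and a fit that took the arrays as independent made 4227. The simulation drew replicate noise independently for each transcript, with the same spread in both genotypes. It took the SD estimated for each transcript from n = 2 per genotype as the true one. Technical noise was added on top, although that SD already holds some. In the data, transcripts moved together by replicate. For these reasons the simulated shares and counts need not hold there.

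The alternatives were both of those fits, the median over technical arrays, leaving out each technical array number and each biological replicate, the replicate number as a block, an intensity trend with a robust prior, no moderation, median centring, quantile normalization again and 2 filters on dim transcripts.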

Results

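Expression was profiled in adult brains of pk^sple1 mutants and Oregon-R controls to find transcripts that differ between the genotypes. The allele carries a spontaneous mutation of prickle, a gene of the planar cell polarity pathway. The data comprised 16 arrays: 8 of sple brains and 8 of control brains, as 2 biological replicates of 4 technical arrays for each genotype. Of 21051 transcripts, 16637 were measured above the floor of the deposited table.

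The 2 sple replicates lay farther apart than the 2 controls. The median SD between replicate means was 0.20 log2 units in sple and 0.12 in control. Across transcripts, which are not independent replicates, the sple replicate means correlated at r = 0.970 and the control means at 0.987. The highest correlation between replicates, 0.992, joined control replicate 1 and sple replicate 1 across genotypes. Sple replicate 2 stood apart from the other 3 replicates on the first principal component, which took 53.9% of the variance. The second component took 26.4% and separated control replicate 2 from sple replicate 1. Technical arrays of 1 replicate lay mostly close together, with median SDs of 0.06 to 0.11 log2 units. The highest, in control replicate 1, was near the 0.12 between the control means. The lowest correlation of arrays within a replicate, r = 0.9923 in control replicate 1, lay below the highest between arrays of different replicates, 0.9929.

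**Figure D1:**
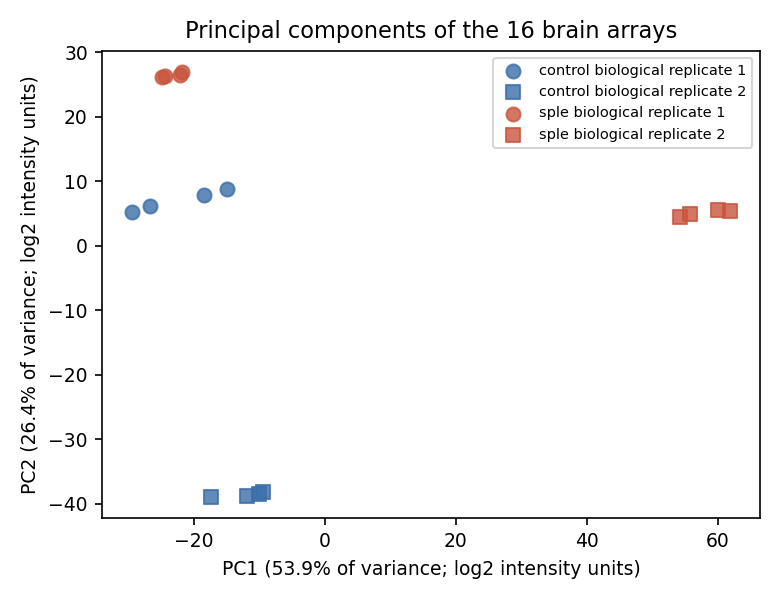
The first 2 principal components of log2 intensity over 16637 transcripts, one point per array, coloured by genotype and shaped by biological replicate. The 4 arrays of each replicate lie together, and sple replicate 2 lies apart along the first component.

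Transcript FBtr0086133 had the highest difference between genotypes among the transcripts the rule took. Its intensity was 14973 ± 2750 (SD, n = 2) in sple brains and 1068 ± 445 (SD, n = 2) in control brains, a log2 difference of 3.86 with a standard error of 0.36. FBtr0074730 followed, with 2412 ± 1719 in sple and 208 ± 105 in control (SD, n = 2) and a log2 difference of 3.43 ± 0.69 (SE). The lowest was FBtr0076454, at 2185 ± 159 in sple and 18728 ± 9473 in control (SD, n = 2), a log2 difference of -3.002 ± 0.41 (SE). FBtr0076496 measured 4091 ± 1078 in sple and 28784 ± 12024 in control (SD, n = 2), a log2 difference of -2.77 ± 0.39 (SE). In these 4 transcripts both sple replicates lay on the same side of both control replicates, as the rule required. The distance was at least 2.06 log2 units. Over all transcripts, genotype separated 8 by at least 4-fold. Splitting the replicates by number instead separated 15, and the remaining split 0. None of the 4 transcripts given above passed limma's test, with an adjusted p of 0.9997 for each. With all 16 arrays in the fit and the biological replicate as a random block, limma's adjusted p of these 4 transcripts was at most 0.000326. That fit made more calls in the simulation without changes, 625, than the 111 it made between the genotypes. The simulated noise differs from that of the data, so this does not decide whether the 111 exceed chance.

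**Figure D2:**
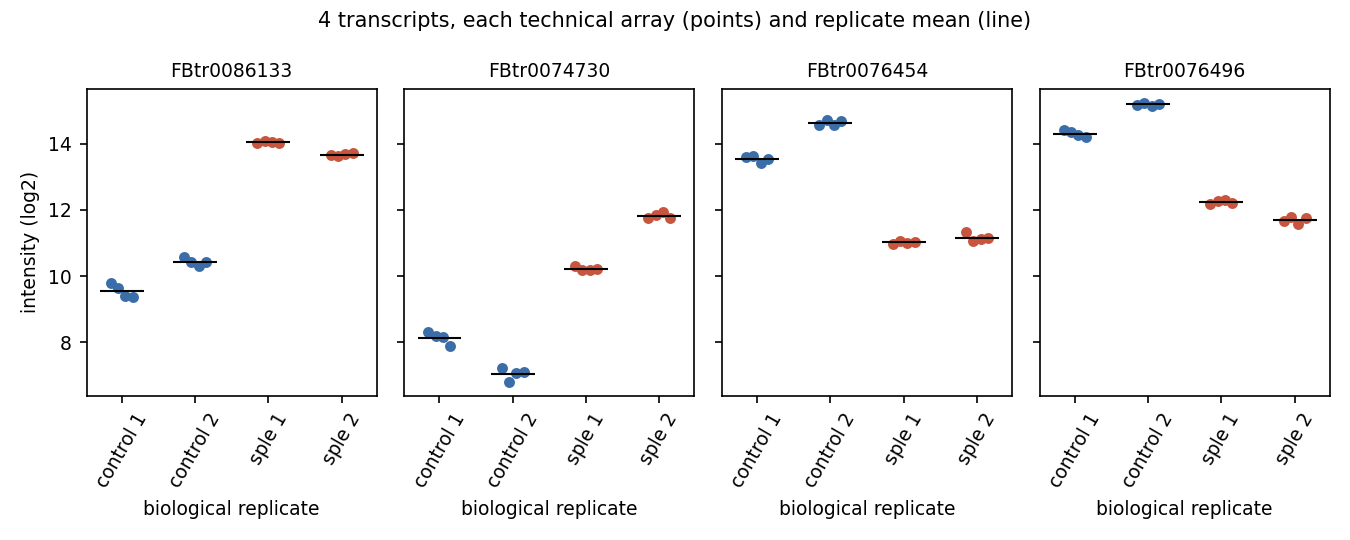
Log2 intensity of 4 transcripts on each of the 16 arrays, with points for technical arrays and lines for the mean of each biological replicate. The smallest distance between a sple and a control replicate mean was 3.24 log2 units for FBtr0086133, 2.08 for FBtr0074730, 2.39 for FBtr0076454 and 2.06 for FBtr0076496.

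Over all measured transcripts, limma called 0 as different between sple and control brains at an adjusted p under 0.05, where the smallest adjusted p was 0.9997. At an unadjusted p under 0.05 there were 413 transcripts, 173 higher and 240 lower in sple, where chance alone gives 832. The mean difference was at least 2-fold for 437 transcripts, of which 341 were higher and 96 lower in sple. Splitting the replicates by number instead gave 611 such transcripts, and the remaining split gave 387. The replicates of the genotypes did not overlap for 27.7% of the transcripts, and chance gives 33.3% for 2 against 2. Every sple replicate was at least 2-fold above every control replicate for 38 transcripts and at least 2-fold below for 10. Among transcripts above the median level these counts were 3 higher and 6 lower, and 46 had a mean difference of at least 2-fold. The median 95% interval reached 0.56 log2 units to either side of a difference.

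Of the 341 transcripts at least 2-fold higher in the sple mean, 150 were at least 2-fold higher in sple replicate 2 than in every other replicate. Another count, 122 of the 341, was at least 2-fold lower in control replicate 2 than in every other replicate. Without sple replicate 1 the 437 became 1542, and the 413 became 3132. The 413 became 740 without sple replicate 2 and 215 without control replicate 2. The 38 transcripts at least 2-fold higher in every sple replicate can only stay or rise in number when a replicate is left out, since fewer pairs must be apart, and became 210, 82, 715 and 146 without control replicates 1 and 2 and sple replicates 1 and 2. The fit with a random block called 111 transcripts, 81 higher and 30 lower in sple. Taking the 16 arrays as independent gave 3417. The simulation without changes gave 625 calls with the random block and 4227 with independent arrays, more than between the genotypes. Its noise differs from that of the data, so it does not decide whether these counts lie above or below chance.

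**Figure D3:**
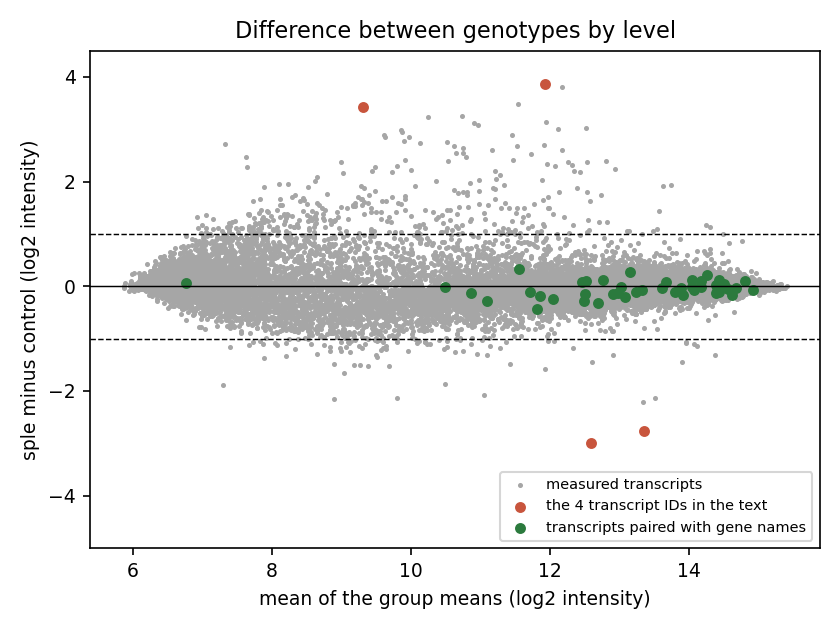
Difference between sple and control (log2 intensity) against the mean of the group means (log2 intensity) for 16637 transcripts, with dashed lines at 2-fold. The 4 transcript IDs given in the text, taken by the rule for their large differences, lie beyond the lines. The 44 transcripts paired with gene names lie between the lines, as do most transcripts.

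Transcripts with gene names differed little between the genotypes, as did most measured transcripts, whose median log2 difference in size was 0.14. Over all 16637, 2.63% had a mean difference of at least 2-fold, and 413 had an unadjusted p under 0.05 by limma. Of the 44 with names, 79.5% lay above the median level, where large differences were fewer. Finding 0 in so small a set therefore says little about these genes in particular. Of the 16 transcripts listed under 1 gene, 5 were higher and 11 lower in sple, and 0 had an unadjusted p under 0.05. Each is 1 transcript and need not stand for every isoform of its gene. Wdr24 and mio, which encode members of a complex that relays amino acid levels to TOR signalling, had the lowest log2 differences, -0.28 ± 0.17 and -0.25 ± 0.20 (SE, n = 2 per genotype). The Wdr24 transcript measured 5262 ± 617 in sple and 6378 ± 184 in control, and the mio transcript 3909 ± 746 in sple and 4608 ± 307 in control (SD, n = 2). The log2 difference was -0.16 ± 0.16 for Uba1, the ubiquitin-activating enzyme, and -0.15 ± 0.26 for sle (SE). It was -0.11 ± 0.18 (SE) for HDAC3, a histone deacetylase.

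On the higher side, rdx, which encodes a substrate adaptor of a cullin ubiquitin ligase, measured 21222 ± 1724 in sple and 18255 ± 1948 in control (SD, n = 2), a log2 difference of 0.22 ± 0.17 (SE). Fatp1, a fatty acid transport protein, had a log2 difference of 0.11 ± 0.17 and NaPi-III one of 0.09 ± 0.15 (SE). The difference was 0.08 ± 0.22 for LanA, a laminin chain of the basement membrane, and 0.07 ± 0.15 for CG31178 (SE). With 1 biological replicate left out in turn, the log2 difference ranged from -0.40 to -0.16 for Wdr24, from -0.44 to -0.053 for mio and from 0.11 to 0.33 for rdx. It ranged from -0.23 to -0.091 for Uba1 and from 0.021 to 0.16 for NaPi-III. For Wdr24 and mio the value nearest 0 was the one without sple replicate 2, where sle was lower than both at -0.45, and for rdx the one without control replicate 1. The signs for HDAC3, sle, Fatp1 and LanA turned when 1 biological replicate was left out, and that for CG31178 when 1 technical array of each replicate was. Adjusted over these 16 alone, the smallest limma p was 0.888. All 16 intervals lay between -0.88 and 0.70 log2 units, so that each excluded a 2-fold difference in measured intensity in either direction. The CG31178 transcript was dim, at 111 ± 6.38 in sple and 105 ± 0.54 in control (SD, n = 2), near the lowest intensity above the floor, 54.84, and its narrow interval does not exclude a 2-fold change of the transcript itself.

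**Figure D4:**
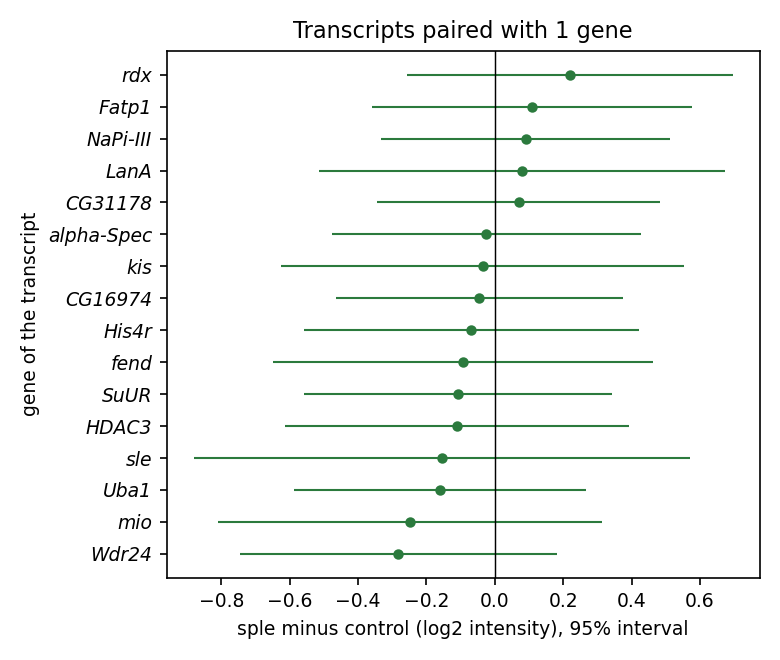
Difference between sple and control brains (log2 intensity) for the 16 measured transcripts listed under 1 gene, with 95% intervals from limma for n = 2 biological replicates per genotype. Every interval includes 0, and the estimates run from -0.28 for Wdr24 to 0.22 for rdx.

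The 28 transcripts listed under several genes had log2 differences from -0.43 to 0.32, with a median of -0.06. In sple, 9 of them were higher and 19 lower, and 0 had an unadjusted p under 0.05. Adjusted over the 28 alone, the smallest limma p was 0.906. The intervals of 26 of the 28 excluded a 2-fold difference in measured intensity.

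**Figure D5:**
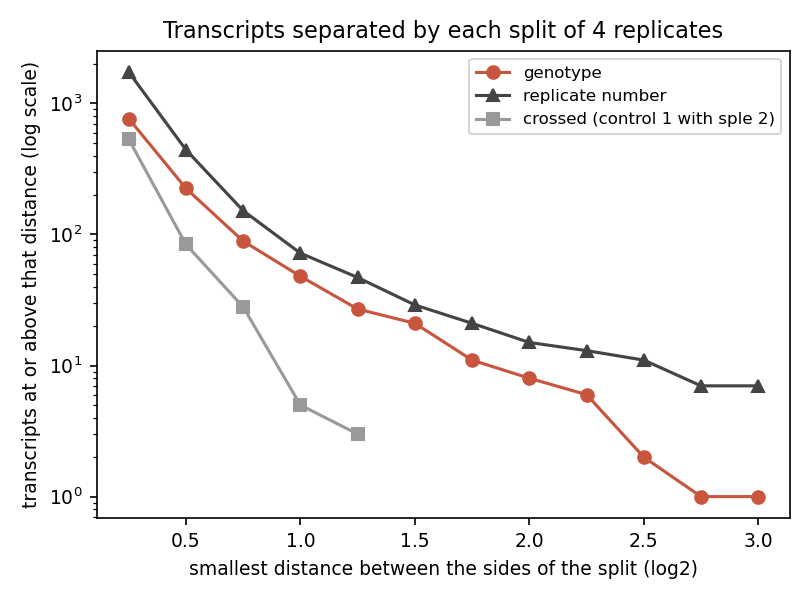
Number of transcripts (log scale) whose 2 sides are separated by at least a given distance (log2 intensity) in each of the 3 ways to split 4 biological replicates into pairs. At a distance of 1, the split by genotype separates 48 transcripts, the split by replicate number 72 and the crossed split 5.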

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

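Among 64 sets of 4 technical arrays, 3 held an array far from the other 3, where chance gives about 1 in 20, or 3.2 sets. In sple replicate 1, the mean correlation of an array with its fellow arrays stood apart with a gap of 0.883 of the range, although all 4 correlations lay near 0.999. The HDAC3 transcript stood apart on 1 array of sple replicate 1 (0.872 of the range), and the Wdr24 transcript on 1 array of sple replicate 2 (0.869 of the range). Groups of 2 biological replicates are too small for this comparison.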

How the results depend on the processing

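All alternatives but one were planned. Keeping the 4414 floor transcripts was added after seeing the data, and raised the 413 transcripts at an unadjusted p under 0.05 to 839 with 0 calls. Calls at an adjusted p under 0.05 were 0 in every averaged fit, and 111 with all 16 arrays and a random block (1337 unadjusted) and 3417 with the arrays taken as independent (6016 unadjusted). The replicate block gave 0 calls and 661 unadjusted. Same-numbered replicates deviated together at r = 0.26 across transcripts, but with 2 pairs and no shared batch in the labels the samples share only a number. The filter at the median level left 181 unadjusted, 46 with a 2-fold mean difference, and 3 higher and 6 lower by 2-fold in every replicate, with fewer transcripts tested. Leaving out 1 biological replicate gave 0 calls each time, with the lone replicate assumed to vary like the other group. The unadjusted count ranged from 215 to 3132, the 2-fold means from 349 to 1542, and transcripts 2-fold higher in every sple replicate from 82 to 715 and lower from 28 to 364, where fewer pairs must be apart. Without 1 technical array number these last counts were as low as 33 and 9. Signs turned, with the log2 difference ranging from -0.15 without control replicate 1 to 0.31 without control replicate 2 for LanA. Without sple replicate 1 and 2 it was 0.14 and -0.45 for sle, -0.0027 and 0.22 for Fatp1, and -0.27 and 0.049 for HDAC3. For CG31178 it was -0.052 without technical replicate 1 and 0.16 without technical replicate 3. The cause was not tested. Of the other values of single transcripts under an alternative, 245 kept direction and side of the threshold, and 11 passed it, each with all 16 arrays in the fit. Median centring moved the median difference from -0.02 to 0.01. The alternatives for pk, for the gene lists and for 1 row per gene were not run, because these IDs are not named here. Transcripts near the floor have little signal over background.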

Other observations

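The comparisons with transcripts of matched level, the ratios other than sple replicate 2 to control replicate 1, the correlation of same-numbered replicates and the counts over other splits were tests chosen only after the results were seen. The other tests were set before their values were seen.

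A set of 68 transcripts was at least 4-fold lower in control replicate 2 than in every other replicate. Their median log2 intensity was 8.19 there, against 11.98 in control replicate 1, 12.96 in sple replicate 1 and 12.06 in sple replicate 2. In 100% of the 68 all 4 arrays of control replicate 2 lay at least 1 log2 unit below every other array, so the 4 arrays shared the low level. The 68 were selected on the mean of these same arrays, which 1 stray array could hardly lower so far. The share is therefore no independent test of noise on single arrays. Transcripts of that level did not fall as a whole, since 652 others of matched level had a median difference of 0.056 log2 units. These were taken outside the set, from values already normalized, so they do not decide whether normalization lowered the 68. One RNA source absent from control replicate 2 may account for the set and stays open: it predicts a fixed ratio between the other replicates, for which an SD under 0.5 log2 units was set as for it and one above 1 as against it. The SD over the 68 was 0.86 for sple replicate 2 minus control replicate 1, 0.42 for sple replicate 1 minus control replicate 1 and 0.88 for sple replicate 2 minus sple replicate 1.

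A set of 134 transcripts was at least 4-fold higher in sple replicate 2 than in every other replicate, with a median log2 intensity of 10.50 there and 7.60 in sple replicate 1. In 94.0% of them all 4 arrays of sple replicate 2 lay at least 1 log2 unit above every other array. These transcripts too were selected on the mean of the same 4 arrays, so the share is no independent test of noise on single arrays. For 1124 other transcripts of matched level the median difference was -0.15 log2 units, so that level did not rise as a whole. These too were taken outside the set, from normalized values, and do not decide whether normalization raised the 134. No biological explanation was tested, since the labels give the 2 sple replicates no difference.

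Splitting the 4 replicates by number separated 72 transcripts by at least 2-fold, of which 67 were higher in replicate 1 of both genotypes. Leaving out transcripts at least 2-fold lower in control replicate 2 than in every other replicate kept 87.5% of the 72, which decides nothing about their part in the split, since the 67 were selected as low in both replicates numbered 2. A batch shared by same-numbered replicates may underlie the split. The replicate differences of both genotypes correlated at 0.34 across transcripts with 805 outliers of single replicates left out. With 2 pairs and no batch in the labels, it cannot be told apart from chance likeness of the replicates.

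The 3 splits of 4 replicates are too few for a share under 0.05. For transcripts at least 2-fold apart, the genotype split gave 48 and the highest other split 72, so that 2 of the 3 splits gave as many. With all 16 arrays and a random block, the genotype split called 111 transcripts and the highest other split 851, and 2 of the 3 splits gave as many. With the arrays taken as independent, the counts were 3417 and 7734, and 3 of the 3 splits gave as many. The highest other counts were those of the split by replicate number. In the simulation without changes, run once for each fit, the random block gave 625 calls and independent arrays 4227. Both lay below the counts of the split by number and above those of the split by genotype. That simulation drew replicate noise independently for each transcript, whereas transcripts in the data moved together by replicate. It therefore does not decide whether any of these counts exceeds chance. In the averaged fit the split by number had 1402 transcripts at an unadjusted p under 0.05, where chance gives 832 and the split by genotype had 413. Whether the replicates share a structure by number stays open.

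Within control replicate 1, technical arrays 1 and 2 were at least 2-fold below arrays 3 and 4 for 105 transcripts and above them for 0.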
